A study of Mus musculus with 10 samples.

How the data were processed

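Total RNA from frozen, sectioned 4T1 tumours was extracted on columns, freed of DNA and of ribosomal RNA and made into sequencing libraries, per the labels' protocols. The table the authors deposited holds gene-level signal values, normalized read counts for 18047 Ensembl genes in 10 libraries. Each library's values are whole multiples of the value of 1 read within 0.0001 of a read (100% of values), and the size factors recovered from them equal the median-of-ratios factors, with a ratio of 1.0 in every library. Base calls were made with bcl2fastq 2.17 and the genome build was GRCm38, per the submitters' processing notes. The sources used here do not give the aligner, the counter, the use of strand or the use of the molecular identifiers in the primers. Floor values therefore cover counting error only, while SD and SE values come from the spread between libraries. The lowest total of any gene in the deposited table is 101 reads. Symbols were taken from the GENCODE M21 annotation of GRCm38 for 17953 IDs, and 94 had none. All coordinates are of GRCm38.

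Samples were grouped by genotype as the labels give it, and all carry the batch label 1. Genes with a mean of at least 10 normalized counts were kept (17975 tested, 72 below). KO was compared with WT in limma 3.58.1 (R 4.3.3) with an intensity trend on log2 of the normalized count plus 1, with Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. Because the deposited values are normalized, this test was the main one, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered whole reads as alternatives. edgeR called 1 gene and DESeq2 121. For a level at 0 in a whole group, the floor was 3 counts per library.

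The designs, 43 gene lists and most alternatives were fixed before the data were examined. The lists cover junctions, carcinoma cells, immune cells and their signals, stroma, neighbouring tissues, pathways and RNA handling. Each list with at least 5 tested members was tested against all other genes with camera (limma, preset correlation 0.01) and again with an estimated correlation, and against no change of its own members with fry. Of the 24 lists called with the preset correlation, 0 were called with an estimated correlation (lowest adjusted p = 0.298) and 0 by fry (lowest adjusted p = 0.262). The median of 1 list and the mean of 3 had another sign than camera, and none of these was called. The list score, the mean log2 level per library, was compared by a two-sided exact permutation test, for which 5 against 5 allows no p below 0.0079. A planned check of the labels and 1 of the gene lists are not reported here. The genes named are every tested claudin, genes past the threshold whose libraries do not overlap (up to 10 in each direction), and up to 4 members of each described list with the smallest p. Genes without a gene name were counted but not named. Acta1, Krt1 and Flg2 were chosen as markers after their values were seen.

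WT2 and WT5 were compared because they share the number 170. Their chi-square per degree of freedom was 142.48, within the range of the WT pairs (38.36 to 177.08), so they were kept as separate libraries. The correlation of their deviations from the group mean, across genes, was -0.241. Deviations from a shared mean lean negative by construction, so that value does not decide the question. Neither value excludes that both libraries came from 1 tumour. The first principal component held 36% of the variance. Across genes, the correlation of a library's deviation with GC content ran from -0.546 in WT5 to 0.635 in WT4, and with log2 length from -0.399 in KO5 to 0.411 in KO1. A correction that removed splines of GC content and length from each library was run as an alternative (17883 tested genes, 99.49%, had both values).

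The limma step was tested on simulated counts for 17975 genes with 200 changed, 5 against 5, in 5 runs. At the dispersion measured in these libraries it recovered 29.2% of changes of log2 size 1 and 94% of those of log2 size 2, with a false share of 4.63%. Alternatives changed the pseudocount, the filter, the scaling, the test, the covariates and the libraries used. After the data were seen, fits were added without the 3 libraries that hold keratinocyte RNA, with keratinocyte and muscle scores as covariates, with the GC and length correction, and with a scaling on nuclear protein-coding genes.

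Of 81 named genes, 17 share exonic bases with another annotated gene, and without a stated strand their reads cannot be told apart from those of the partner. In 4 cases the partner codes for protein: Cd247 shares 3007 bases with Pou2f1, Cxcl10 133 with Art3, Hk3 34 with Unc5a, and Gbp8 61 with Gbp4 and 60 with Gbp9. Reads of near-identical family members (Klrc1 and Klrc2, Gbp8, Tgtp2, Stfa2, the H2 genes and the keratins) could be split between copies by the counting, so their single values are uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.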

Results

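RNA was sequenced from tumours of 4T1, a mammary carcinoma line of BALB/c mice, that had grown for 3 weeks in mice. In 5 libraries the tumours came from cells with a gene knocked out, and in 5 from wild-type cells. The series title asks about claudins and about the exclusion of immune cells, so the comparison of knockout (KO) with wild-type (WT) tumours addresses tight junction genes and immune cell genes. Normalized read counts were given for 18047 genes. The reads behind them came to 8609756 in KO1, 13559976 in KO2, 9544524 in KO3, 13682815 in KO4 and 16066866 in KO5. The WT libraries held 15029869 reads in WT1, 15488306 in WT2, 11772430 in WT3, 19934428 in WT4 and 11804937 in WT5. The labels number the libraries and tie none to a named animal, so p-values measure the spread between these libraries. The library names of KO5 and of WT1 to WT4 begin with RESUB, a prefix the labels do not explain, so fits within the prefixed libraries hold 1 KO library and fits within the others 1 WT library, whose spread cannot be measured. WT2 and WT5 share the library number 170.

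Cobl, which encodes an actin nucleator, was the 1 gene past the threshold, and it fell by 2.43 ± 0.29 (SE) on the log2 scale in the KO tumours. The gene (ENSMUSG00000020173) lies on chromosome 11 from 12236608 to 12464960, on the minus strand. It had 24.97 ± 7.22 normalized counts in KO and 139 ± 38.8 in WT (SD, n = 5 each), and every KO library was below every WT library (limma adjusted p = 0.025). No gene passed as higher in KO: limma called 0 of 17975 higher, with 507 higher and 659 lower at an unadjusted p under 0.05, where chance alone gives 899 in total. edgeR called 1 gene, lower in KO, and DESeq2 called 121, of which 26 were higher and 95 lower. The KO and WT libraries did not overlap for 255 genes (123 higher, 132 lower), 1.419% of those tested, where chance gives 0.794%. Leaving out KO1, KO2, KO3, KO4, WT3, WT4 or WT5 ended the call of Cobl, with log2 differences of -2.47, -2.48, -2.45, -2.54, -2.36, -2.53 and -2.35 and limma adjusted p of 0.0923, 0.0704, 0.106, 0.0501, 0.146, 0.0738 and 0.0821. Among the WT libraries Cobl was highest in WT2, WT3 and WT5, which hold keratinocyte RNA. It was at 91.4 and 101.4 normalized counts in WT1 and WT4. Its call was also lost without those 3 libraries, at -1.96 (limma adjusted p = 0.513). With the keratinocyte score as a covariate it was lost at -2.00 (limma adjusted p = 0.653). Over the alternatives the adjusted p of Cobl ran from 3.04e-11 to 0.653. Leaving out WT2 gave 3 genes, Cobl, Dsc2 and Myo5b, all lower. With the RESUB prefix as a term limma called 1 gene, and the difference of Cobl was -2.87. Within the prefixed libraries, where KO5 is the only KO library, it was -3.17. Within the others it was -2.56, with WT5, which holds keratinocyte RNA, as the only WT library. Averaging the pair numbered 170 left 0 genes, with 1292 at an unadjusted p under 0.05.

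**Figure D1:**
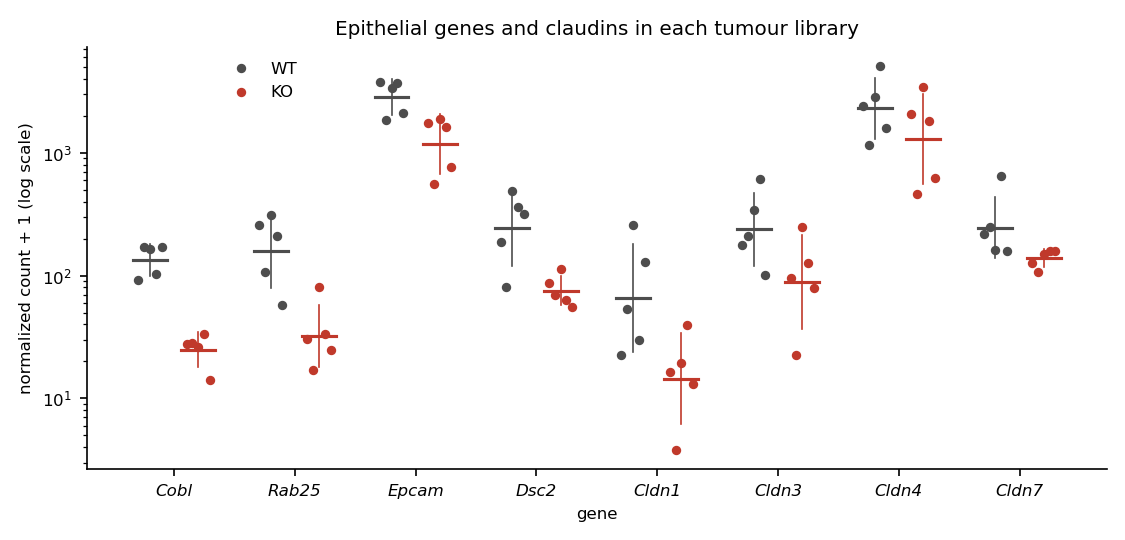
Normalized counts plus 1, on a log scale, of the epithelial genes Cobl, Rab25, Epcam and Dsc2 and 4 claudins in each of the 5 WT (grey) and 5 KO (red) libraries; horizontal lines are means and vertical lines SD of the log values. The KO libraries of Cobl (24.97 against 139 normalized counts on average) lie below every WT library, and those of the 4 claudins overlap them.

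Genes of the epithelial carcinoma cell were lower in the KO tumours. All 26 tested members of the carcinoma and epithelial list had lower fitted values, with a median log2 difference of -1.0 (camera adjusted p = 1.96e-15; adjusted p = 0.298 with an estimated correlation). Adjusted over the list alone 7 passed as lower. Adjusted over all genes 0 did in limma, with 16 lower at an unadjusted p under 0.05, and 0 in edgeR, while DESeq2 called Rab25 and Krt14 as lower. Rab25, a small GTPase of apical membrane recycling, had 36.3 ± 25.3 normalized counts in KO and 188 ± 106 in WT (log2 -2.31 ± 0.49 SE, adjusted p = 0.011 over the list alone). Epcam, an epithelial adhesion molecule, had 1317 ± 613 against 2956 ± 923 (log2 -1.26 ± 0.36). Krt14 and Krt5, keratins of basal epithelium, had log2 differences of -1.85 and -4.62. Krt5 was at 210, 2020 and 269 normalized counts in WT2, WT3 and WT5, the libraries with keratinocyte RNA, against 30.8 and 83.3 in WT1 and WT4, and KO4 held 81.8. Without those 3 libraries the differences were -1.27 and -2.68. The mean log2 level of the list was 7.02 ± 0.72 in KO and 8.27 ± 0.61 in WT (SD, n = 5 each; exact permutation p = 0.0079, 0.171 adjusted over the lists). The median was -1.30 with the RESUB prefix as a term, -1.90 within the prefixed libraries and -0.67 within the others. Keratinocyte genes moved with this group: Krt1 was at 0 in 7 libraries and at 44.6, 1152 and 343 normalized counts in WT2, WT3 and WT5, and without these 3 libraries the list median was -1.13.

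The 11 tested claudins, the membrane proteins that seal tight junctions, had a median log2 difference of -0.70, with 8 lower and 3 higher (camera adjusted p = 0.00622; adjusted p = 0.298 with an estimated correlation). The carcinoma and epithelial list fell further, at a median of -1.0, and the claudins were not tested against it. A smaller share of carcinoma cells in the KO tumours therefore cannot be told apart from a lower claudin level in those cells. Of the 11 claudins, 0 passed in limma adjusted over the claudin list alone or over all genes, and 3 had an unadjusted p under 0.05, all lower. Over all genes edgeR called 0 claudins and DESeq2 called Cldn1 as lower (adjusted p = 0.037, and 0.037 to 0.9995 over the alternatives). Cldn1 had 17.5 ± 13.3 normalized counts in KO and 97.6 ± 98.3 in WT (log2 -2.18 ± 0.71 SE), Cldn3 113 ± 83.4 against 288 ± 202 (-1.44 ± 0.58) and Cldn7 139 ± 22.9 against 286 ± 205 (-0.82 ± 0.34). Cldn4, the most abundant, had 1674 ± 1198 against 2605 ± 1522 (-0.82 ± 0.53). The differences of Cldn15, Cldn23, Cldn2 and Cldn12 were -0.75, -0.70, -0.28 and -0.24, and those of Cldn10, Cldn5 and Cldn20 were 0.57, 0.32 and 0.057. Cldn1 moved with the keratinocyte genes, at 52.8, 256 and 128 normalized counts in WT2, WT3 and WT5 against 21.6 and 29.0 in WT1 and WT4. The mean log2 level of the list was 5.73 ± 0.37 in KO and 6.30 ± 0.35 in WT (exact permutation p = 0.0318, 0.228 adjusted over the lists). The median was -0.45 without KO2 and -0.33 without KO4. Among single claudins, Cldn3 was at -0.95 and Cldn4 at -0.45 without KO2, Cldn4 at -0.53 and Cldn7 at -0.47 without WT4, Cldn15 at -0.33 without KO4 and Cldn10 at 0.30 without KO5. Cldn5 was at 0.60, 0.20, 0.06 and 0.073 without KO1, KO2, KO5 and WT5. With 1 library left out Cldn2 ran from -0.57 to 0.062 and Cldn20 from -0.20 to 0.30. The list median was -0.51 with the RESUB prefix as a term (camera adjusted p = 0.0882), -0.79 within the prefixed libraries (0.0355) and -0.17 within the others (0.435), where the call was lost, and the adjusted p ran from 0.000954 to 0.435 over the alternatives.

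Genes of adherens junctions and desmosomes, which hold epithelial cells together, were lower in 19 of 21, with a median log2 difference of -0.59 (camera adjusted p = 3.91e-08; adjusted p = 0.334 with an estimated correlation). Adjusted over the list alone 7 passed as lower. Over all genes 0 did in limma, with 9 lower at an unadjusted p under 0.05, and 0 in edgeR, while DESeq2 called 5 as lower. Perp, a desmosomal membrane protein, had 391 ± 144 normalized counts in KO and 1226 ± 550 in WT (SD, n = 5; log2 -1.65 ± 0.32 SE, adjusted p = 0.00347 over the list alone). The desmosomal cadherins Dsc2 and Dsg2 had log2 differences of -1.69 and -1.34. Dsc3, another, moved with the keratinocyte genes: it was at 71.9, 1326 and 450 normalized counts in WT2, WT3 and WT5, at 0.83 in WT1 and at 0 in WT4 and in all 5 KO libraries. Of the other tight junction genes 16 of 21 were lower, with a median of -0.25 (camera adjusted p = 0.00195; adjusted p = 0.371 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Among them Marveld3, a tight junction membrane protein, had a log2 difference of -1.53, Cgn, which encodes cingulin, -0.87, the polarity gene Pard6b -0.67 and Ocln, which encodes occludin, -0.66. The median of these other tight junction genes was -0.17 without KO5 and, with the call lost, -0.25 within the libraries without the RESUB prefix (camera adjusted p = 0.271, the highest of the alternatives, whose lowest was 1.58e-06). Without the 3 libraries with Krt1 reads the 2 medians were -0.85 and -0.40.

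RNA of neighbouring normal tissue differed between libraries. All 13 tested skin and hair genes were lower in KO and all 13 passed adjusted over the list alone, with a median log2 difference of -3.38, or -2.69 with the 5 members at 0 in KO set to the floor (camera adjusted p = 1.38e-13; adjusted p = 0.298 with an estimated correlation). This list was carried by WT2, WT3 and WT5: the call was lost without them at a median of 0.00, with the keratinocyte score as a covariate at 0.15 and with both scores at 0.029. Flg2, a gene of the cornified skin surface, had 77.4, 716 and 815 normalized counts in those libraries and 0 in the other 7, and Dsg1a, an epidermal desmosomal cadherin, had 111, 1158 and 576, with 2.172 in WT4 and 0 in WT1 and in all 5 KO libraries. Krt79, a keratin of the hair follicle, had 0.69 against 102 normalized counts on average. All 20 skeletal muscle genes were lower in KO, with a median of -1.92 and 0 past the threshold adjusted over the list alone (camera adjusted p = 6.41e-06; adjusted p = 0.507 with an estimated correlation). Acta1, the actin of skeletal muscle, ran from 0 in KO3 and 1.94 in WT3 to 27351 in WT2. Myh1 and Eno3, a myosin heavy chain and an enolase of muscle, had log2 differences of -2.59 (-1.59 without KO3) and -1.02 (-0.48 without WT2). The muscle median was -1.01 without KO3, -0.96 without WT2 and -3.30 without WT3. Of 16 adipocyte genes 15 were lower, with a median of -1.21 and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.000189; adjusted p = 0.543 with an estimated correlation). Lep, which encodes leptin, and Plin1, a coat protein of lipid droplets, had log2 differences of -2.26 and -2.18 (Plin1 -1.24 without KO2 and -1.23 without KO5), and without KO5 the median was -0.48 (camera adjusted p = 0.0652) and the call was lost. Of 9 Schwann cell and nerve genes 8 were lower, with a median of -0.38 and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00803; adjusted p = 0.298 with an estimated correlation), which was -0.27 without KO5, where the call was lost, and -0.16 without WT2. Within the libraries without the prefix the adipocyte and nerve calls were lost at -0.29 and -0.24, with sample weights at -0.87 and -0.23, while within the prefixed libraries they were kept at -4.49 and -0.88. The muscle call was lost within the prefixed libraries at -0.72 and with the muscle score or both scores as covariates at -0.043 and -0.048. Over all alternatives the adipocyte, nerve and muscle medians ran from -4.49 to -0.29, from -0.88 to -0.16 and from -3.30 to -0.043.

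**Figure D2:**
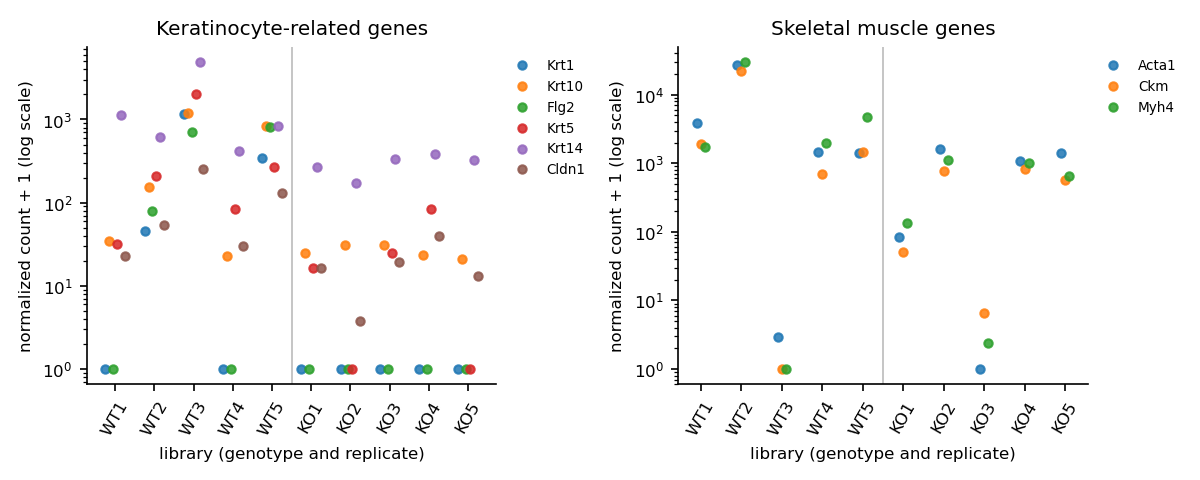
Normalized counts plus 1, on a log scale, of keratinocyte-related genes (left) and skeletal muscle genes (right) in each of the 10 libraries, 1 point per gene and library. Krt1 and Flg2 have counts in WT2, WT3 and WT5 and stand at 0 in the other 7 libraries, and Acta1 is highest in WT2 at 27351.

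Targets of interferon gamma, the cytokine of activated T and NK cells, were higher in the KO tumours. Of 29 tested genes 28 were higher, with a median log2 difference of 0.57 (camera adjusted p = 1.89e-14; adjusted p = 0.298 with an estimated correlation), and 2 passed adjusted over the list alone. Over all genes 0 passed in limma, with 12 higher at an unadjusted p under 0.05, and 0 in edgeR, while DESeq2 called Cxcl9 as higher. Cxcl9, a chemokine that draws activated T cells, had 2331 ± 815 normalized counts in KO and 1087 ± 310 in WT (SD, n = 5 each; log2 1.08 ± 0.26 SE, adjusted p = 0.0284 over the list alone). The interferon-inducible GTPase Iigp1 had 6277 ± 2090 against 3146 ± 1147 (log2 1.01 ± 0.26, adjusted p = 0.0284 over the list alone). The related GTPases Gbp8 and Tgtp2 had log2 differences of 0.93 and 0.64. The mean log2 level of the list was 9.95 ± 0.20 in KO and 9.37 ± 0.50 in WT (exact permutation p = 0.0556), and WT3, at 10.16, lay within the range of the KO libraries. The type I interferon list was not called: 15 of 30 genes were higher and 15 lower, with a median of 0.021 (camera adjusted p = 0.501). It was called as higher without WT3 (0.19), with sample weights (0.18), without the 3 libraries with Krt1 reads (0.21) and with the keratinocyte score (0.31), and as lower with the muscle score (-0.13). The median of the interferon gamma list was 0.69 with the RESUB prefix as a term, 0.88 within the prefixed libraries, 0.42 within the others and 0.80 without the 3 libraries with Krt1 reads.

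Of the 14 immune lists 10 were called by camera, 9 higher and 1 lower, and with an estimated correlation 0 were (lowest adjusted p = 0.298). NK cell genes were higher in 9 of 12, with a median log2 difference of 0.52 (camera adjusted p = 0.000437; adjusted p = 0.298 with an estimated correlation) and 3 past the threshold adjusted over the list alone. These 3 were the lectin-like receptor genes Klrc1, Klrd1 and Klrc2, at log2 1.33, 1.05 and 1.30, and Klrc1 had 117 ± 59.0 normalized counts in KO and 43.6 ± 16.6 in WT (SD, n = 5). The 3 genes lie close together on chromosome 6, from 129591782 to 129678973. The median of the 15 Mb window that holds them was 0.24 higher in KO after removal of GC and length trends. T cell genes were higher in 19 of 22, with a median of 0.53 (camera adjusted p = 4.55e-05; adjusted p = 0.371 with an estimated correlation), among them the developmental gene Themis (1.04) and the T cell receptor signalling genes Cd247 (0.89) and Lck (0.65), while the transcription factor gene Bcl11b was at -1.05 (-0.67 without WT3, which held 180.6 of its normalized counts against at most 65.4 in any other library). None of the T cell genes passed adjusted over the list alone (0 of 22 in limma, with 5 higher and 1 lower at an unadjusted p under 0.05). CD8 and cytotoxic genes were higher in 12 of 16, with a median of 0.66 (camera adjusted p = 0.00201; adjusted p = 0.371 with an estimated correlation). The cytotoxic effector genes Prf1, Nkg7 and Fasl had log2 differences of 1.03, 1.02 and 0.81, and Eomes, a transcription factor of cytotoxic cells, was the 1 member past the threshold adjusted over the list alone, and it was lower (-1.15, adjusted p = 0.0323). Regulatory T cell and checkpoint genes were higher in 15 of 17, with a median of 0.35 (camera adjusted p = 0.000597; adjusted p = 0.334 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Tnfrsf9, a costimulatory receptor, had 596 ± 413 against 250 ± 32.2 normalized counts, and Cd274, Pdcd1 and Ctla4, the genes of PD-L1, PD-1 and CTLA-4, had log2 differences of 0.77, 0.68 and 0.62. The T cell median was 0.35 without WT5. By the mean level per library the exact permutation p was 0.0238 for NK cell and 0.111 for T cell genes. It was 0.127 for CD8 and 0.119 for checkpoint genes. The T cell levels of WT3 and WT4, 5.72 and 5.62, lay within the KO range of 5.26 to 6.14. Within the libraries without the RESUB prefix the NK cell call was lost at 0.58 (camera adjusted p = 0.0647, the highest of the alternatives, whose lowest was 2.17e-05). Keratinocyte and muscle scores as covariates ended the T cell, CD8 and checkpoint calls at medians of 0.35, 0.23 and 0.26.

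**Figure D3:**
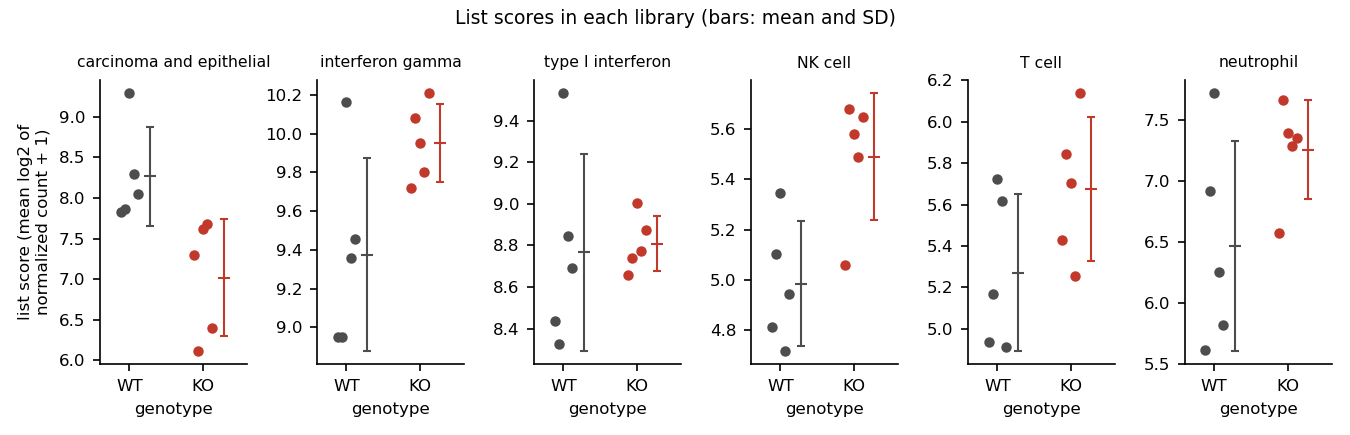
Mean log2 of the normalized count plus 1 over the members of 6 lists in each WT (grey) and KO (red) library, with the mean and SD of each group of 5 beside the points. The carcinoma and epithelial list is lower in KO (7.02 against 8.27), the interferon gamma list is 9.95 against 9.37 with WT3 among the KO values, and the type I interferon list is 8.81 against 8.77.

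Neutrophil genes were higher in 25 of 26, with a median log2 difference of 0.80 (camera adjusted p = 1.88e-07; adjusted p = 0.334 with an estimated correlation) and 0 past the threshold adjusted over the list alone in limma (4 higher and 0 lower at an unadjusted p under 0.05). The granule gene Ngp, the cystatin gene Stfa2 and the surface marker Ly6g had log2 differences of 1.5, 1.54 and 1.51 (Ngp 0.97 and Ly6g 0.90 without WT1), and the cytokine gene Il1b had 1158 ± 377 normalized counts in KO and 710 ± 483 in WT (SD, n = 5). Ly6g rested on few reads, at 15.6 ± 7.45 normalized counts in KO and 6.83 ± 6.86 in WT. It was at 0 in WT1 and at 18.2 in WT2, within the KO range of 8.39 to 26.7. The mean log2 level of the list was 7.26 ± 0.41 in KO and 6.47 ± 0.86 in WT (exact permutation p = 0.111). WT3, at 7.72, lay above all 5 KO libraries, and WT2, at 6.92, above KO1 at 6.57. On recovered reads the neutrophil median was 0.37 in edgeR and 0.36 in DESeq2. MHC class II genes, which present antigen to CD4 T cells, were higher in 11 of 12, with a median of 0.35 (camera adjusted p = 0.000627; adjusted p = 0.371 with an estimated correlation) and 0 past the threshold adjusted over the list alone. H2-Aa had 15555 ± 2089 against 9939 ± 1591 normalized counts, and H2-DMb1, H2-Eb1 and the lysosomal protease gene Ctss had log2 differences of 0.50, 0.41 and 0.36. Without WT1 the MHC class II call was lost at a median of 0.24 (camera adjusted p = 0.0613, the highest of the alternatives, whose lowest was 3.66e-09). Chemokines were higher in 22 of 29, with a median of 0.33 (camera adjusted p = 0.00326; adjusted p = 0.371 with an estimated correlation), and Cxcl9 alone passed adjusted over the list alone (adjusted p = 0.0358). Ppbp, a platelet chemokine, Ccl12, which draws monocytes, and Cxcl10, an interferon target, had log2 differences of 1.24, 0.83 and 0.56 (Cxcl10 0.37 without WT1). The chemokine median was 0.58 without KO1, 0.20 without KO4, 0.53 without WT2, 0.18 without WT3 and 0.20 without WT5, where the call was lost (camera adjusted p = 0.0708). On reads tested in edgeR it was lost at 0.17 (adjusted p = 0.0554), and the adjusted p ran from 3.47e-05 to 0.0708 over the alternatives. MHC class I genes were higher in 16 of 20, with a median of 0.15 (camera adjusted p = 0.0185; adjusted p = 0.65 with an estimated correlation) and 0 past the threshold adjusted over the list alone. That call was lost without KO2 (0.14), KO4 (0.12), KO5 (0.081), WT1 (0.087), WT2 (0.12) or WT5 (0.054), and the median was 0.25 without KO1 and 0.24 without WT4. It was also lost with the pair numbered 170 averaged (0.095), without the 3 libraries with Krt1 reads (0.064) and with the keratinocyte score (0.078), the muscle score (0.076) or both (0.029) as covariates.

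Mast cell, eosinophil and basophil genes were lower in 7 of 9, with a median log2 difference of -0.51 (camera adjusted p = 0.00272; adjusted p = 0.371 with an estimated correlation). The mast cell protease gene Mcpt4 had 25.5 ± 17.9 normalized counts in KO and 103 ± 79.2 in WT (SD, n = 5; log2 -1.90 ± 0.54 SE) and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0325). The other mast cell protease genes Tpsb2, Cpa3 and Cma1 had log2 differences of -1.70, -1.35 and -1.32. The median was -0.89 without KO4 and -0.79 without WT5. The call was lost within the libraries without the RESUB prefix (-0.088, camera adjusted p = 0.953), with sample weights (-0.47, 0.437), without the 3 libraries with Krt1 reads (-0.65, 0.0761), with the keratinocyte score as a covariate (-0.83, 0.0688) and with both scores (-0.69, 0.166), and the adjusted p ran from 4.73e-05 to 0.953 over the alternatives. The macrophage list was not called, with a median of 0.19 (camera adjusted p = 0.115), nor were the fibroblast list at -0.097 and the pericyte and smooth muscle list at -0.32, though each was called in some alternatives (macrophage 0.30 without WT2, fibroblast -0.32 without WT3, pericyte -0.41 without KO3). Over all genes limma and edgeR called 0 members of the 14 immune lists, and DESeq2 called Cxcl9, Klrc1 and H2-Aa as higher and Eomes and Mcpt4 as lower. In all, camera called 24 of 43 lists, 12 higher and 12 lower, and with the mean level per library as the unit 0 passed (exact permutation, lowest adjusted p = 0.171, 7 at an unadjusted p under 0.05). Among the called lists the unadjusted exact permutation p was 0.103 for proliferation, 0.19 for MHC class II, 0.214 for chemokine and 0.31 for adipocyte genes. For muscle, MHC class I, ribosomal protein and replication histone genes it was 0.325, 0.341, 0.373 and 0.579. The medians of the 19 lists not called ran from -0.39 to 0.19.

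**Figure D4:**
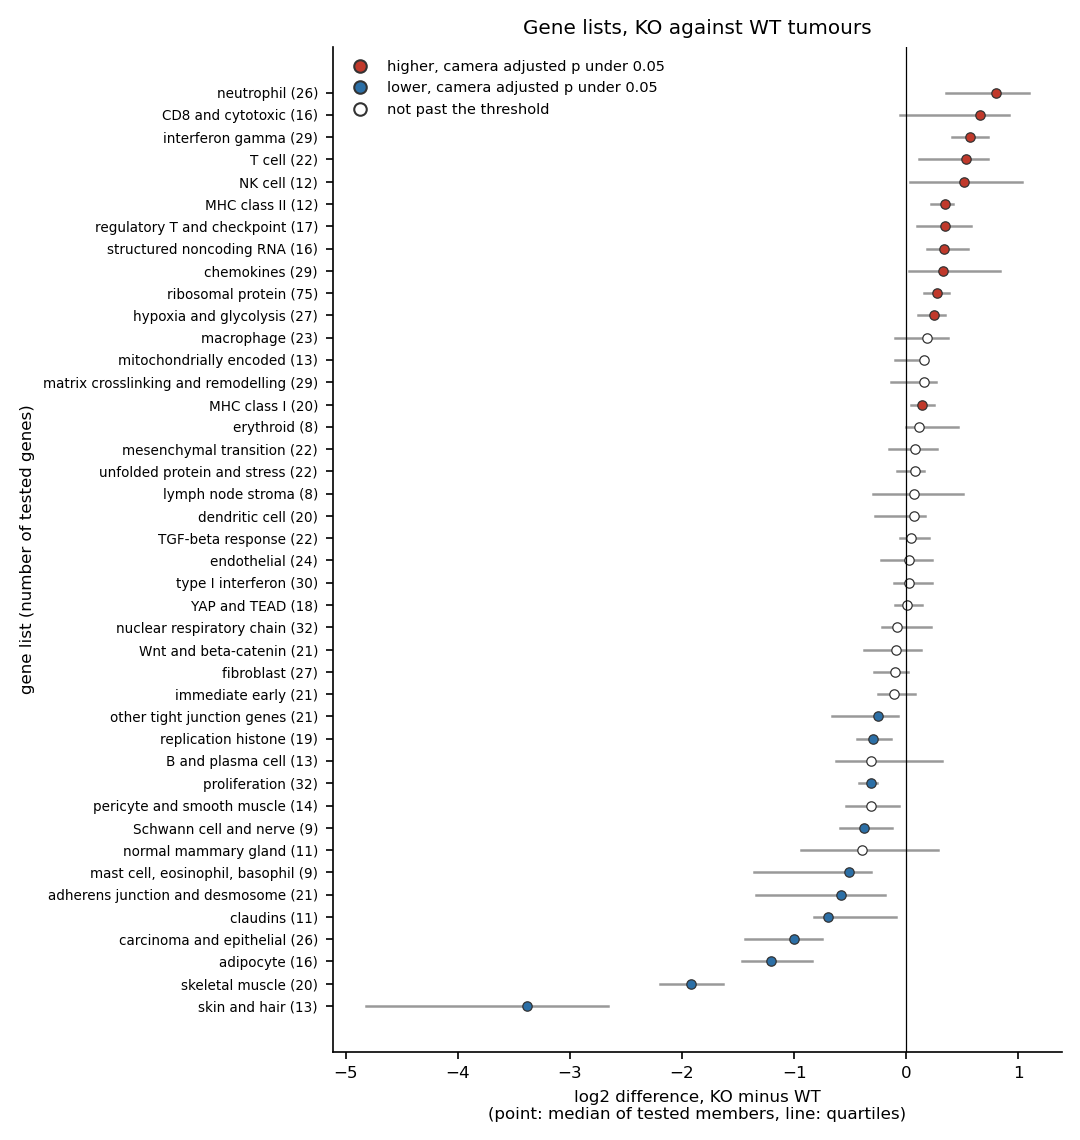
Median log2 difference, KO minus WT, over the tested members of each gene list (points) with the quartiles of the members (lines); filled points are past a camera adjusted p of 0.05, red higher and blue lower. The carcinoma and epithelial list is at -1.0 and the interferon gamma list at 0.57.

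All 32 tested members of the proliferation list, genes of cell division, had lower fitted values in KO, with a median log2 difference of -0.31 (camera adjusted p = 1.33e-07; adjusted p = 0.371 with an estimated correlation), and 0 passed adjusted over the list alone in limma (4 lower at an unadjusted p under 0.05). The mitotic kinase genes Aurkb and Plk1 had log2 differences of -0.63 and -0.53 (Plk1 -0.33 without WT4), and Mcm6 and Mcm5, of the replicative helicase, -0.56 and -0.46. Mcm6 had 1564 ± 559 normalized counts in KO and 2221 ± 358 in WT (SD, n = 5). The median was -0.20 without KO3, 0.072 within the prefixed libraries, where the call was lost, and -0.62 within the others. Hypoxia and glycolysis genes were higher in 21 of 27, with a median of 0.25 (camera adjusted p = 0.00195; adjusted p = 0.484 with an estimated correlation) and 0 past the threshold adjusted over the list alone. It was 0.16 without KO2, and the call was lost at 0.20 without KO5 and 0.19 without WT1. Ribosomal protein genes were higher in 68 of 75, with a median of 0.27 (camera adjusted p = 2.94e-08; adjusted p = 0.65 with an estimated correlation), which was 0.44 without KO1, 0.15 without KO5 and 0.44 without WT2. Structured noncoding RNAs, whose level can follow library preparation, were higher in 15 of 16, with a median of 0.34 (camera adjusted p = 0.000286; adjusted p = 0.298 with an estimated correlation; exact permutation p of the mean level = 0.0079). That call was lost within the libraries without the prefix, at 0.13. Replication histone genes were lower in 17 of 19, with a median of -0.30 (camera adjusted p = 0.0477; adjusted p = 0.867 with an estimated correlation). The histone call was lost without KO1 (-0.085), KO2 (-0.21), KO3 (-0.19) or WT1 (-0.25), the sign turned without WT2 (0.036), and the median was -0.60 without KO5, -0.48 without WT3 and -0.47 without WT5. It was also lost with a pseudocount of 10, a filter at a mean of 50, edgeR, DESeq2, the replicate number as a block, the pair numbered 170 averaged or the 3 libraries with Krt1 reads left out, at medians of -0.32 to -0.30. The sign also turned with the prefix as a term (0.39) and within the prefixed libraries (0.63), where the list was called as higher, within the others (0.083) and with the muscle score (0.073) or both scores (0.02) as covariates. The ribosomal protein, noncoding and histone lists each had 0 members past the threshold adjusted over the list alone in limma, with 2, 4 and 1 at an unadjusted p under 0.05.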

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

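The tests that weigh the epithelial pattern here were all chosen only after the result was seen.

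Of 208 groups of 5 values examined, 20 had a library far from the other 4. The limit used gives about 1 in 20 by chance for independent, normally distributed values. Gene values were examined as normalized counts without a log, and the groups share libraries, so the 20 are not shown to exceed chance. WT3 was the highest WT library for Perp (2200 normalized counts), Krt14 (4869, next 1134), Krt5 (2020, next 269), Krt79 (394), Bcl11b (180.6), Klrc1 (72.8) and Stfa2 (80.6). It was also the lowest for the mean level of the proliferation list (9.56, next 10.09). WT4 was the highest WT library for Cldn7 (646.6, next 249), Pard6b (227), Aurkb (642) and Plk1 (762). WT2 was the highest for the muscle genes Myh1 (3486) and Eno3 (5250.0). Among the KO libraries, KO3 was the highest for Rab25 (80.2), KO5 for Lck (233), Iigp1 (9922) and Cxcl10 (429), and KO2 for Zfp57 (176). KO1 had the lowest KO level of the MHC class II list (9.69).

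The carcinoma and epithelial list was lower in KO while WT2, WT3 and WT5 held keratinocyte RNA. Without those libraries its median was -1.13, and after removal of GC and length trends -0.93, against -1.0 in the main fit. The kept size argues against keratinocyte RNA and against GC or length as the whole cause. Camera called both medians at the preset correlation. For Cldn1 the difference shrank from -2.18 to -0.85 without those libraries, and WT1 and WT4 lay within the KO range, so keratinocyte RNA may account for most of it. A smaller share of carcinoma cells in the KO tumours stays open: the list fell by 0.81 ± 0.47 (SE) more than Krt8 and Krt18, genes chosen after their values were seen (exact permutation p = 0.143). The mean score of leukocyte lists minus that of stromal lists was 0.43 ± 0.22 (SE) higher in KO than in WT (exact permutation p = 0.0556). An effect of the knockout on epithelial identity is a hypothesis that cannot be told apart from that share here, because that excess over Krt8 and Krt18 lay within the spread between libraries.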

How the results depend on the processing

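The fits without the libraries that hold keratinocyte RNA, with tissue scores as covariates, with the GC and length correction or scaled on nuclear protein-coding genes were chosen only after the data were seen; the others were planned. The cause was not tested for any change below unless stated.

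The main count of 1 gene was 408 with sample weights (233 higher, 175 lower; weights 0.379 for WT2 to 5.43 for WT1), 121 in DESeq2, 52 in the libraries without the RESUB prefix, 77 with the muscle score, 11 with both scores and 3 with the GC and length correction. It was 0 in limma in the prefixed libraries, with the pair numbered 170 averaged, without the keratinocyte-bearing libraries and with the keratinocyte score (682 to 1292 genes at an unadjusted p under 0.05). Leaving out each library in turn gave 0 to 3. In the prefixed and unprefixed sets the lone library, KO5 and WT5 respectively, is assumed to vary like the others. WT5 holds keratinocyte RNA, so the genes called in the unprefixed set cannot be ascribed to the genotype. The 24 lists and 10 immune lists were both 0 with an estimated correlation and 0 by fry, and the immune lists were 5 with both scores. Leaving out each library gave 8 to 11 immune lists.

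The claudin median was negative in every alternative and lost its call with the prefix as a term (-0.51), in the unprefixed libraries (-0.17), with an estimated correlation (-0.70) and by fry (-0.70). Leaving out each library gave -0.83 to -0.33.

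The replicate numbers do not pair the libraries (correlations across genes of 0.017, 0.099, 0.518, 0.026 and -0.229; 2 of 10 libraries matched their own number best). With the replicate number as a block 1 gene passed, Cobl did not (adjusted p = 0.118) and the claudin median was -0.70; with the GC and length correction in the same fit 2 genes passed, both lower, and the claudin median was -0.66. In the latter the type I interferon median was -0.0046 and Cldn20 -0.043.

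Medians that changed sign were these. The skin and hair list was 0.00 without the keratinocyte-bearing libraries, 0.15 with the keratinocyte score and 0.029 with both scores, as its construction requires. Proliferation was 0.072 and Mcm6 0.13 in the prefixed libraries. The histone list was 0.39 with the prefix as a term, 0.63 in the prefixed and 0.083 in the unprefixed libraries, 0.073 with the muscle score, 0.0204 with both scores and -0.60 to 0.036 leaving out each library. Macrophage genes were -0.022 with the keratinocyte score. Type I interferon genes were -0.015 in edgeR, -0.021 in DESeq2, -0.038 with the pair averaged, -0.13 with the muscle score, -0.0046 with the GC and length correction and -0.041 to 0.19 leaving out each library. Fibroblast genes were 0.059 and pericyte genes 0.11 in the unprefixed libraries, and fibroblast genes -0.32 to 0.023 leaving out each library. Cldn5 was -0.050 without the keratinocyte-bearing libraries and -0.11 with both scores. Cldn2 was 0.24 with sample weights and -0.57 to 0.062 leaving out each library. Cldn20 was -0.34 with the prefix, -0.061 with the pair averaged, -0.74 in the prefixed libraries, -0.34 with the muscle score, -0.22 with both scores, -0.043 with the GC and length correction and -0.20 to 0.30 leaving out each library.

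For the other list medians 755 values kept their side of the threshold, 47 lost the call and 32 gained it; for single genes the numbers were 2416, 15 and 81. The planned fit with a correlation for the pair numbered 170 could not be estimated from 1 pair. At 8609756 to 19934428 reads per library, limma recovered changes of log2 size 1 in 29.2% of simulated genes. In such simulated data, with each gene drawn on its own, most changes of that size were thus missed by this test. Recovery was not simulated for edgeR, DESeq2 or sample weights.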

Other observations

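The tests of the interferon and chromosome patterns, and the counts of other splits, were all chosen only after the result was seen.

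These genes had a small unadjusted p in limma without passing adjusted over all genes, and they were chosen after their values were seen. Zfp57, a zinc finger protein that maintains genomic imprints, had 140 ± 21.1 normalized counts in KO and 50.9 ± 13.7 in WT (SD, n = 5 each; log2 1.47 ± 0.22 SE, limma adjusted p = 0.14). Ccnd2, which encodes cyclin D2, had 2865 ± 298 against 1589 ± 218 (log2 0.85 ± 0.16, adjusted p = 0.307). Rgs1, a regulator of G protein signalling in leukocytes, the semaphorin gene Sema7a and the hexokinase gene Hk3 had log2 differences of 1.62, 1.35 and 1.04 (adjusted p = 0.307, 0.373 and 0.418). On the lower side Ppp1r14c, an inhibitor of protein phosphatase 1, had 125 ± 36.0 against 327 ± 62.8 (log2 -1.41 ± 0.23, adjusted p = 0.142). Myo5b, a motor of apical membrane recycling, was at -2.17 and Fgfbp1, a carrier of fibroblast growth factors, at -1.48 (adjusted p = 0.307 each). DESeq2 and limma with sample weights called all 8 of these genes, and edgeR called none of them. The GC and length correction called Zfp57 and Ccnd2, leaving out WT2 called Myo5b, and the muscle score as a covariate called Zfp57, Rgs1, Ppp1r14c, Myo5b and Fgfbp1. Over the alternatives the adjusted p ran from 2.89e-06 to 0.896 for Zfp57, from 7.63e-05 to 0.996 for Ccnd2 and from 3.35e-05 to 0.831 for Ppp1r14c.

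At the preset correlation camera did not call the type I interferon list and called the interferon gamma list as higher. The interferon gamma list was not called with an estimated correlation (camera adjusted p = 0.298) or by fry (adjusted p = 0.262). Its score exceeded the type I score by 0.53 ± 0.094 (SE) more in KO than in WT (exact permutation p = 0.0079, the smallest possible), which argues against an equal rise of all interferon targets. The median was 0.53 after removal of GC and length trends, against 0.57 in the main fit. This argues against such trends as the whole cause. With the RESUB prefix as a term the median was 0.69, but only KO5 and WT5 separate the prefix from the genotype. Handling marked by the prefix is therefore not excluded. Camera called both medians at the preset correlation. Interferon gamma made by more NK and T cells in the KO tumours is a candidate explanation, and it was not tested beyond the cell lists. WT3, whose score lay among the KO values, keeps the difference of the score itself at an exact permutation p of 0.0556.

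Genes of chromosomes 6, 12 and 14 were together slightly higher in the KO tumours, while those of 16 and 19 differed by 0.045 and -0.10 at the same exact permutation p of 0.0079. After removal of GC and length trends the differences of the chromosome medians were 0.17, 0.20 and 0.18 on the log2 scale, with every KO library above every WT library (exact permutation p = 0.0079 each, 0.0318 adjusted over 20 chromosomes, and 0.0529 adjusted without the correction), which argues against GC content or length as the cause. All 27 windows of 15 Mb on these chromosomes were higher, against 55 of 159 on the other 17 chromosomes, so the rise ran along their length. The percentage of genes higher was 80%, 82.2% and 81.2% on them and 29.5% to 59% on the others. The windows and the percentages both follow in part from picking these chromosomes for their higher medians. Chromosome 16 had 5 of 7 windows higher, and chromosomes 8, 11 and 19 had 0 of 9, 0 of 9 and 0 of 5, so a shift along a whole chromosome was also seen downwards. On chromosome 12 KO2, KO4 and KO5 stood at 0.23, 0.12 and 0.17 from the mean of all libraries, but KO1 and KO3 at -0.042 and 0.0015, near WT3 at -0.057. A difference in copies of these chromosomes between the KO and WT cells may account for the rise. The medians are relative to all libraries, so they do not tell a gain in KO cells from a loss in WT cells. On chromosome 12 the share of KO cells with a gain would have to differ between the KO tumours. No DNA measurement was used here.

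Among 100 splits of the 10 libraries into 5 and 5, the real one included, 4 gave at least the 1 gene called. That share is under 0.05, but it rests on a count of 1, which fell to 0 in some fits with 1 library left out. It therefore does not exclude chance for that count. The highest other split gave 441 genes. That split set KO1, KO2, KO3, WT3 and WT5 against the rest, and 96 splits gave 0 genes in limma, so the libraries hold a structure that is not the genotype. For the 24 lists 14 splits gave as many (highest other 27), and for the 10 immune lists 13 did (highest other 11), so chance cannot be excluded for either count. The split by the RESUB prefix gave 0 genes, 8 lists and 1 immune list.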
